A study of Rattus norvegicus with 6 samples.

How the data were processed

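Total RNA from the hypothalamus of rats was reverse transcribed with radioactively labelled dATP and a Clontech primer mix, per the labels' protocols, and hybridised to arrays. The labels name 6 conditions with 1 sample each: the untreated euhydrated control, 2 days and 30 days of heat acclimation, hypohydration by water deprivation, and both heat stages with hypohydration. Some labels describe rats before and during heat, so the exact time of sampling is taken only as the named stage. The array design, the scanner, the image software, the background correction and the authors' normalization and filter are not given in the sources used here.

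The authors deposited 1 table of processed intensities, with 884 probes in rows and 6 samples in columns, none of it missing, zero or negative. The values are read as linear intensities because they are positive and skewed to the right. What each column was divided by, whether values were centred per probe and whether a column averages several arrays stay unknown. The lowest value is repeated in some columns (0.01 at 14 probes in the 2-day euhydrated sample, 0.0287 at 7 in the control and 0.0544 at 6 in the 30-day euhydrated sample). The 2-day hypohydrated sample holds 0.01 at 36 probes and 3 lower values, down to 0.00868, so whether a floor was set before deposition stays unknown. All columns belonged to the samples of the series. The identifiers are 508 with the prefix R and 376 with the prefix RG. None matched a gene identifier, symbol, synonym, transcript or Ensembl identifier in the rat gene table (assembly GRCr8), so no gene is named and the planned tests of 27 gene lists could not be run.

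The design, the settings, the rule for named probes and the alternatives were fixed before the data were examined, except where a comparison or an alternative is said to be added. The values were to be used as deposited if the sample medians of log2 intensity agreed within 0.1, or if they were log values or ratios. The medians differed by 0.88 over 546 probes above the floor in all samples. Whether the values are ratios stays unknown, and for ratios the rule would keep the deposited values as the main setting. With the values read as intensities, the main setting was quantile normalization between samples (limma 3.58.1 in R 4.3.3). It gives each sample the same distribution and removes any overall shift. Values under the 10th percentile of all values, 0.143 after normalization, were set to that floor before log2. On the deposited scale this floor was 0.0941. A fold against a sample at the floor is a lower bound. Probes were kept if the mean of their 6 values exceeded the 25th percentile of probe means (0.338), which left 663.

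Each group holds 1 sample, so a difference between 2 samples has no replicate check and no p-value. Such comparisons are reported as counts of probes at least 2-fold higher or lower among the kept probes above the floor in at least 1 of the 2 samples. There were 7 planned comparisons and 2 added after the values were seen. Changes were set against each other only where the 2 differences share no sample, in 5 planned correlations and 1 added. Their bootstrap SD comes from 1000 draws of probes and describes probes, not animals. An additive model of heat stage (3 levels) and hydration (2 levels) was fitted to all 6 samples with lmFit and eBayes of limma, at a Benjamini-Hochberg adjusted p of 0.05. It uses the heat stages as stand-ins for replicates of hydration and the hydration states as stand-ins for replicates of heat. The model tests the average effect over them, and a response to hypohydration that depends on the heat stage counts as error. Because limma pools this error in part across probes, a probe that changes mainly in 1 stage can still be called. Nothing says whether the samples came from separate or pooled animals.

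With no gene symbols, the rule for named probes allowed 2 probes in each direction per comparison, those with the largest change among kept probes above the floor on both sides. For the additive model they were those with the smallest p. For changes shared by all heat stages or both hydration states they were those with the largest smallest change. R608 and RG415, named for the fit without the 2-day stage, follow the same rule but were chosen after their values were seen.

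The scripts were tested on simulated data with 200 changed probes and a median noise SD of 0.66 log2 units, over 663 probes past the filter. For hypohydration 50% of 4-fold and 89.5% of 8-fold changes were recovered, with 9 false calls among 97. For 2 days of heat 12.2% of 4-fold, 44.7% of 8-fold and 78.4% of 16-fold changes were recovered, with 0 false calls among 51. For 30 days these shares were 2.78%, 19.0% and 55.3%, with 1 false call among 31. Each test was simulated with 1 random draw. The tests of 2 and of 30 days have the same design, so their gap in recovery is a difference between draws. The simulated noise was independent between samples and held no response to hypohydration that depends on the heat stage. Alternatives were the values as deposited, scaling to a common median, a floor at the 25th percentile, no filter, a filter at the median of probe means, an intensity trend in eBayes, no block for the heat stage, and leaving out each heat stage or each sample. Leaving out each sample was added and not planned. So was leaving out both 2-day samples for the 30-day test and for a correlation. Figures were drawn with matplotlib 3.10.9.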

Results

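The data were 6 rat hypothalamus samples that crossed 2 hydration states with 3 heat stages. Heat acclimation is the adjustment of an animal to sustained exposure to heat, and the hypothalamus is the brain region that sets body temperature, thirst and water balance. The heat stages were no heat, 2 days (short-term acclimation) and 30 days (long-term acclimation). Hypohydration was a loss of 10% of body weight through water deprivation. The sample hypohydrated without a heat exposure in its label is called unheated here, like the euhydrated control. Each of the 6 groups held 1 deposited column of processed array intensities for 884 probes. The series text counted 9 arrays per hydration state against 3 columns, so a column may combine several arrays. No error within a group could be computed, so the precision is unknown, and sequencing depth does not apply to arrays. The files do not pair the probe identifiers with genes, and 0 of the 884 matched the rat gene table used here. Probes are therefore named only by identifier, with no position in the genome, and the 27 gene lists fixed in advance could not be tested.

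The deposited values differed between samples in level and in spread. The median intensity was 0.397 in the unheated euhydrated control, 0.451 at 2 days and 0.353 at 30 days of heat. In the hypohydrated samples it was 0.686 without heat, 0.473 at 2 days and 0.565 at 30 days. The SD of log2 intensity over probes was 1.49 in the control and 1.35 at 30 days in euhydrated rats. It was 1.89 and 2.14 in the euhydrated and hypohydrated 2-day samples, and 0.66 and 0.99 in the unheated and 30-day hypohydrated samples. Both 2-day samples repeated the value 0.01, at 14 probes in the euhydrated sample, where it was the lowest, and at 36 in the hypohydrated sample, where 3 probes lay below it. The medians lay 0.88 log2 units apart over the probes above the floor in all samples. With the values read as intensities and not as ratios, the comparisons below therefore used quantile-normalized values.

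The first comparison asked how alike the 6 hypothalamus profiles were. The most alike samples were the unheated and 30-day hypohydrated ones, with a Spearman correlation across 884 probes of 0.84. The euhydrated control and the 30-day euhydrated sample followed at 0.69, and the 2 samples of 2 days at 0.67. The euhydrated control and the 2-day euhydrated sample were the least alike of the 15 pairs of samples, at 0.09. The 2-day samples correlated with the other 4 samples at between 0.09 and 0.42. For the 2-day euhydrated sample this was 0.35 and 0.42 with the unheated and 30-day hypohydrated samples. With the unheated and 30-day euhydrated samples it was 0.09 and 0.18. The 2-day hypohydrated sample had 0.29 and 0.29 with the hypohydrated and 0.29 and 0.24 with the euhydrated samples, in the same order. Of the variation in log2 intensity over the 663 probes past the filter, 60.3% lay between heat stages, 14.3% between hydration states and 25.3% in the remainder. With no effect these shares would be 40%, 20% and 40%. The remainder holds noise together with any differing combination of heat stage and hydration. The contrast of 2 days with the other heat stages alone held 52.7%, against 20% with no effect. These are correlations and shares across probes, which are not independent replicates, so no p-value was attached.

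**Figure D1:**
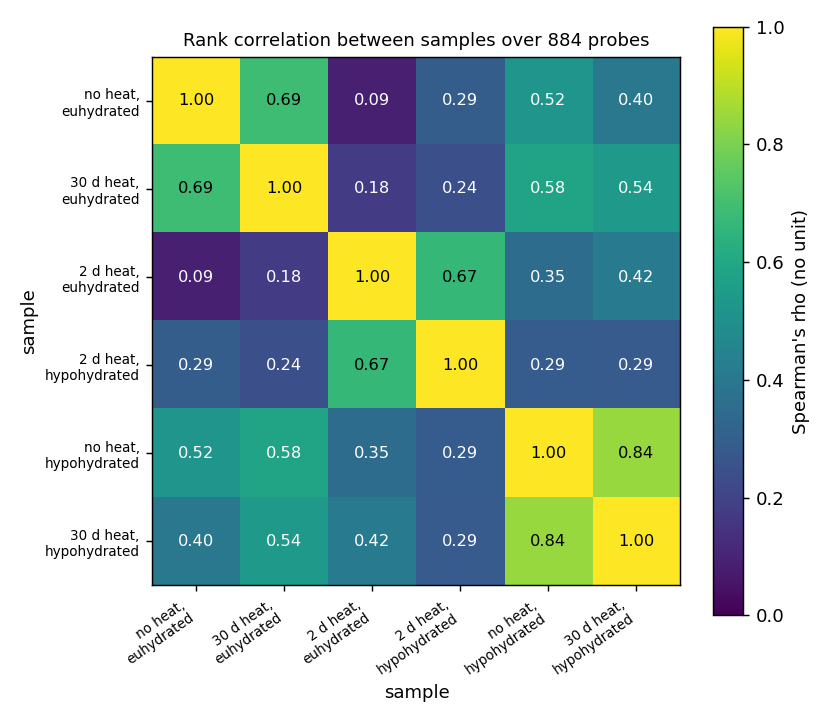
Heat map of Spearman's rank correlation (no unit) between each pair of the 6 samples over 884 probes of deposited intensity, with 1 sample on each row and column. The 3 highest values off the diagonal are 0.84, 0.69 and 0.67, and the lowest, 0.09, is between the euhydrated control and the 2-day euhydrated sample.

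Short-term heat acclimation was compared with no heat in each hydration state. In euhydrated rats, 199 of 663 probes were at least 2-fold higher after 2 days and 191 were at least 2-fold lower, together 58.8%. Probes R155 and R052 were 11.9-fold and 11.5-fold higher, and R685 and R349 were 27.6-fold and 25.4-fold lower. With median scaling the split was 184 and 260, and in the deposited values R685 and R349 were at least 49.2-fold and 48.1-fold lower, with the 2-day value under the floor of that scale (0.0941). In hypohydrated rats 154 probes were at least 2-fold higher and 169 at least 2-fold lower, and with the values as deposited this split was 74 and 205, and with median scaling 96 and 190. Probes R369 and R289 were 30.5-fold and 26.3-fold higher there, and RG437 and R455 were 14.1-fold and 13.1-fold lower. In the deposited values R369 and R289 were 11.5-fold and 11.1-fold higher, RG437 was at least 19.1-fold lower, with the 2-day value under the floor, and R455 was 18.8-fold lower. The changes of the 2 hydration states, which share no sample, correlated across 558 probes with Pearson's r = 0.38 (bootstrap SD over probes 0.039) and Spearman's rho = 0.32. Each change uses a sample from the alike 2-day pair, so anything shared by that pair raises this correlation.

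An additive model of heat stage and hydration over the 6 samples tested for a 2-day change common to both hydration states. In limma, 70 of 663 probes passed a Benjamini-Hochberg adjusted p of 0.05, of which 31 rose and 39 fell. With the values as deposited 10 rose and 50 fell, and with median scaling 8 and 45. All 70 were at least 2-fold different in the same direction in both hydration states, and their median fold was 6.09. The call itself favours such agreement, since it averages the 2 states and takes disagreement between them as error. The smallest fold called was 4.29. Probe R289 rose by 4.02 log2 units (SE 0.70, limma adjusted p = 0.00136) and R369 by 3.87 (SE 0.71, adjusted p = 0.00186). Probe R675 fell by 4.43 log2 units (SE 0.68, limma adjusted p = 0.000554) and R318 fell by 4.15 (SE 0.67, adjusted p = 0.000712). Both lay at the floor in the 2 samples of 2 days, so these fitted values depend on the floor. The differences from no heat were at least 24.0-fold and 19.4-fold for R675 in euhydrated and hypohydrated rats, and at least 17.8-fold in each for R318. The test takes as error the remainder, which holds noise and any differing combination of heat stage and hydration, on 2 residual degrees of freedom. To these limma added 22.2 prior degrees of freedom from the variances of all probes, 24.2 in total. Anything shared by the 2 samples of 2 days also counts as a 2-day change. When each sample was left out in turn, the count was 0 without either of the 30-day samples. It fell without either unheated sample and rose without either 2-day sample. The runs without an unheated or a 2-day sample leave a single sample in a compared stage, so they do not test a change common to both hydration states. The runs without a 30-day sample do test it, since they keep both unheated and both 2-day samples. The fitted 2-day change is the same there, and only its error estimate differs. The 70 calls therefore depend on an error estimate to which both 30-day samples contribute.

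Long-term heat acclimation gave smaller differences from no heat. In euhydrated rats, 87 of 655 probes were at least 2-fold higher after 30 days and 66 at least 2-fold lower, together 23.4%. The split was 77 and 114 with the values as deposited. Probes R596 and R670 were 5.79-fold and 5.24-fold higher, and R518 and RG478 were 4.84-fold and 4.57-fold lower. The 30-day value of RG478 (0.145) lay just above the floor (0.143). With the floor at the 25th percentile its log2 difference was -1.51. In hypohydrated rats 36 of 653 probes were at least 2-fold higher and 37 at least 2-fold lower, together 11.2%, the fewest of all comparisons. With the values as deposited this split was 1 and 62, and with median scaling 8 and 27. Probes R075 and R111 were 3.77-fold and 3.71-fold higher and RG307 and R292 were 3.84-fold and 3.76-fold lower. The higher values of R075 and R111 were 1.64-fold and 1.77-fold in the deposited values. The 2 changes correlated across 585 probes with r = 0.16 (bootstrap SD 0.039) and Spearman's rho = 0.16, and with r = 0.28 in the values as deposited.

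The additive model in limma called 0 probes for 30 days against no heat, and 11 of 663 had an unadjusted p under 0.05, where 33.2 would be expected by chance. A count below chance can mean that the error is too large for this contrast. The error includes the hypohydration change at 2 days, which ran against the other stages (given below). The 0 calls are therefore no evidence that nothing changed at 30 days. With either or both of the 2-day samples left out, 74 had an unadjusted p under 0.05 and 0 were called. The smallest adjusted p in limma was 0.994. RG478 had log2 differences of -2.19 in euhydrated and -1.30 in hypohydrated rats, with a model value of -1.75 (SE 0.68, limma adjusted p = 0.994). R432 was 1.22 and 1.69 log2 units higher in the 2 hydration states and did not pass the test. Of the 70 probes called at 2 days, 53 in euhydrated and 64 in hypohydrated rats were less than 2-fold different from no heat at 30 days, and 5 and 0 were at least 2-fold different in the opposite direction. R289 had 30-day log2 differences of -0.97 in euhydrated and 0.86 in hypohydrated rats. The median change was 2.61 log2 units at 2 days and 0.01 at 30 days for the 31 that rose, and -2.61 and -0.12 for the 39 that fell. On average over the hydration states, 7 of the 70 were still at least 2-fold different in the same direction at 30 days. The 70 were chosen for their 2-day values, which enlarges those, and both changes use the same unheated samples, which pulls the 30-day values the same way.

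The 2 acclimation stages were also compared directly, a comparison added after the values were seen. From 2 to 30 days, 185 of 663 probes were at least 2-fold higher in euhydrated rats and 180 at least 2-fold lower. With median scaling this split was 257 and 158, and with the values as deposited 191 and 241. In hypohydrated rats 167 were at least 2-fold higher and 155 at least 2-fold lower, and 214 and 118 with median scaling and 197 and 135 as deposited. The changes in the 2 hydration states correlated across 559 probes with r = 0.42 (bootstrap SD 0.040) and rho = 0.35. The alike 2-day samples enter this correlation too, and anything they share raises it. Probe RG437 was 3.29 and 4.06 log2 units higher at 30 days than at 2 days in the euhydrated and hypohydrated samples, and R289 had log2 differences of -4.30 and -3.86.

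**Figure D2:**
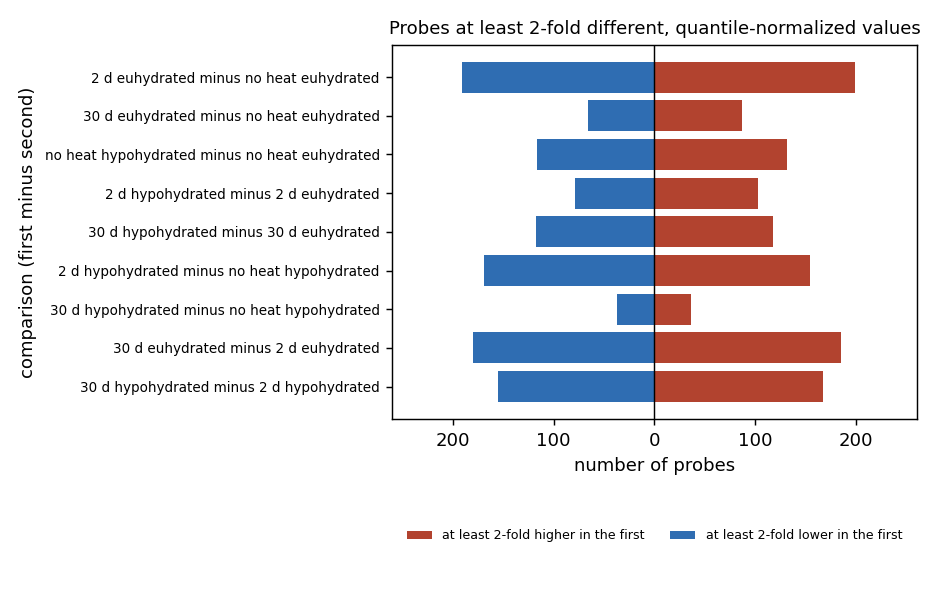
Bars give the number of probes at least 2-fold higher (right, red) or lower (left, blue) in the first than in the second sample of each comparison, on quantile-normalized intensities of probes past the filter, with 1 sample per group and no error. The 2-day sample against the control in euhydrated rats has 199 and 191 probes, and the 30-day against the unheated sample in hypohydrated rats has 36 and 37.

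Hypohydration was compared with euhydration at each heat stage. Without heat, 131 of 661 probes were at least 2-fold higher in the hypohydrated sample and 117 at least 2-fold lower, together 37.5%. Probes R596 and RG500 were 9.07-fold and 7.03-fold higher, and R325 and R693 were 7.93-fold and 5.24-fold lower. The lower values of R596, RG500 and R325 (0.17, 0.15 and 0.15) lay near the floor of 0.143. For R596 this is the control value that also entered its rise at 30 days of heat. In the deposited values RG500 was 11.01-fold higher and R325 and R693 were 3.30-fold and 2.19-fold lower. At 2 days of heat 103 of 658 probes were at least 2-fold higher and 79 at least 2-fold lower, together 27.7%. Probes R485 and RG400 were 5.38-fold and 5.17-fold higher there, and RG045 and R104 were 6.14-fold and 5.88-fold lower. In the deposited values R485 and RG400 were at least 8.92-fold and 10.1-fold higher and RG045 at least 12.8-fold lower, with the lower value of each under the floor. At 30 days 118 of 661 probes were at least 2-fold higher and 118 at least 2-fold lower, together 35.7%. Probes R103 and R666 were 7.61-fold and 7.34-fold higher at 30 days, and RG013 and R017 were 5.71-fold and 5.51-fold lower, and 3.19-fold and 2.80-fold in the deposited values. The lower values of R103 and R017 (0.155 and 0.144) lay just above the floor after normalization. With the values as deposited the split of higher and lower probes was 223 and 27 without heat and 201 and 49 at 30 days, and the median difference of all kept probes was 0.42 and 0.43 log2 units. With median scaling it was 125 and 160 without heat and 110 and 152 at 30 days. At 2 days it was 144 and 103 as deposited.

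The hypohydration changes of the 3 heat stages share no sample and could be set against each other. The change without heat and the change at 30 days went together, with Pearson's r = 0.60 across 585 probes (bootstrap SD 0.028) and the same sign at 70.8% of probes. The change at 2 days ran against both. Its correlation was r = -0.34 with the change without heat (558 probes, bootstrap SD 0.035, the same sign at 36.9%). With the change at 30 days it was r = -0.24 (559 probes, bootstrap SD 0.036, the same sign at 40.1%). Spearman's rho was 0.60, -0.34 and -0.24 for these comparisons. The differences without heat and at 30 days both set the 2 alike hypohydrated samples (0.84) against the 2 alike euhydrated samples (0.69), so anything shared by the members of a pair raises their correlation.

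Few probes differed in one direction with hypohydration at every heat stage. Of 531 probes above the floor in all samples, 4 were at least 1.5-fold higher and 14 at least 1.5-fold lower in all 3 stages, where unrelated changes would give 11.1 and 10.2. Probe RG292 had log2 differences of -1.39, -2.26 and -1.66 without heat, at 2 days and at 30 days. RG453 was 1.24, 0.87 and 1.04 log2 units higher. In the additive model limma called 0 probes for hypohydration, and 42 of 663 had an unadjusted p under 0.05, where 33.2 would be expected by chance. In simulated data 8.32% of unchanged probes had a p under 0.05 in this test. RG292 had a model value of -1.77 (SE 0.55, limma adjusted p = 0.697).

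Without the 2-day stage the same limma model called 154 of 663 probes for hypohydration, 86 that rose and 68 that fell. RG415 rose by 2.62 log2 units and R666 by 2.61, and R608 fell by 2.57 and R325 fell by 2.54 (SE 0.48 and limma adjusted p = 1.51e-05 for each). R608 lay at the floor in a sample of every stage and RG415 in a 30-day sample, so these fitted values depend on the floor. At 2 days R608 was at least 1.79 and R325 was 2.34 log2 units higher in the hypohydrated sample. Of 151 called probes with a 2-day value, 114 had the opposite sign at 2 days and 37 the same sign. That fit has 1 residual degree of freedom, and limma then used 1 common variance for all probes. A probe's own disagreement between the stages without heat and at 30 days therefore did not count against it. Leaving out the unheated or the 30-day stage instead called 0 probes.

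**Figure D3:**
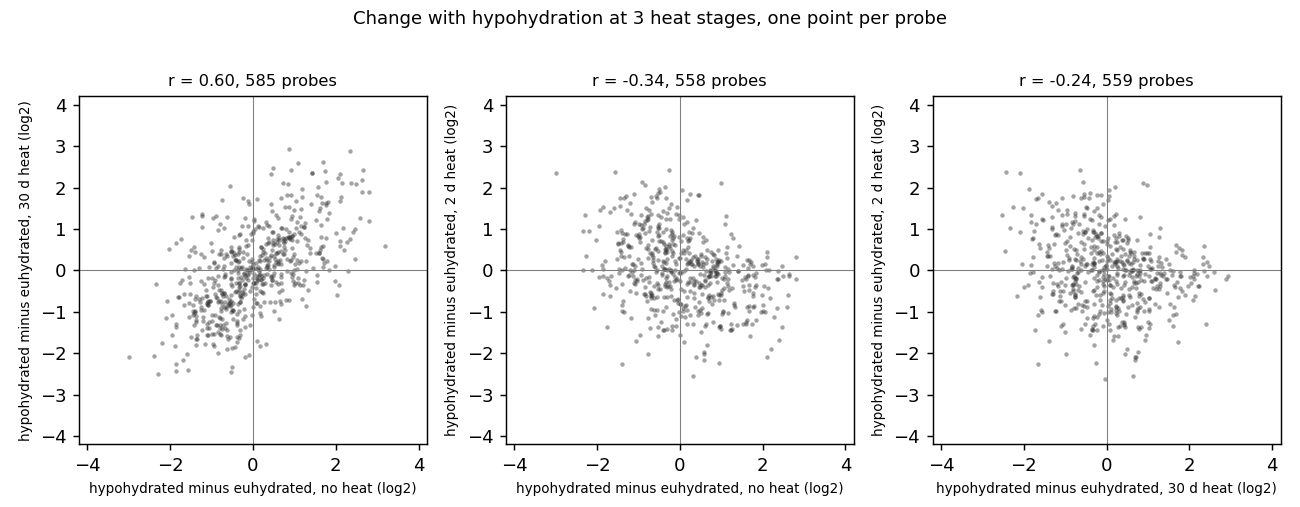
Each point is a probe, with the hypohydrated minus euhydrated difference in log2 intensity at one heat stage on the x axis and at another on the y axis, 1 sample per group, for probes above the floor in the 4 samples of each panel. The differences without heat and at 30 days go together (r = 0.60), and the 2-day difference runs against the differences without heat (r = -0.34) and at 30 days (r = -0.24).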

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

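The correlations between the hypohydration changes were planned, and the tests of explanations in this part were chosen after the results were seen.

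The change with hypohydration at 2 days of heat ran against the change in the other heat stages, with a correlation across probes of -0.34 against the change without heat and -0.24 against the change at 30 days. The difference between stages was not tested, and each group holds 1 sample. Among the probes named for hypohydration, 5 were at least 2-fold different in opposite directions at 2 stages. Their hypohydrated minus euhydrated log2 differences are given in the order no heat, 2 days and 30 days. R325 had -2.99, 2.34 and -2.10, a span of 5.33. R596 had 3.18, -2.54 and 0.58, a span of at least 5.72, since its 2-day hypohydrated value lay at the floor. R608, with a value at the floor at every stage, had -2.53, 1.79 and -2.61, a span of at least 4.40. RG013 had -2.28, 1.33 and -2.51, a span of 3.85, and RG400 had -1.57, 2.37 and -2.42, a span of 4.79.

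These explanations were weighed for this opposition. Processing that differed between the pairs of similar samples, equally for both members of a pair, predicts a 2-day change unrelated to the others. The observed correlation was -0.34 (bootstrap SD 0.034 in a separate bootstrap run). It cannot decide, because it is the pattern itself and its SD describes probes. How far from 0 unrelated differences between single samples would fall is unknown. A pair-specific effect whose strength differed within the 2-day pair also stays open. The 2-day change correlated with the level of the 30-day euhydrated sample at 0.060 (bootstrap SD 0.039), too close to 0 to decide. With the level of the 30-day hypohydrated sample it correlated at -0.19, a value for which no prediction had been set. Interchanged labels of the 2-day samples cannot be told apart from a real reversal, because an interchange only turns the sign of the correlations (-0.24 with the change at 30 days) and no probe could be tied to a gene of known response. A response to hypohydration that itself depends on the heat stage is the biological explanation the design offers, and it is untested.

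A second pattern is the grouping of the samples into 3 pairs that follow neither hydration nor heat alone: control with 30-day in euhydrated rats, unheated with 30-day in hypohydrated rats, and the samples of 2 days. Values at the floor in the 2-day samples are argued against as the whole cause. The check used 376 probes above the floor in all samples and bright in the unheated and 30-day hypohydrated samples. Among them the control correlated at 0.75 with the 30-day and at -0.15 with the 2-day euhydrated sample. That is a gap of 0.90 (bootstrap SD 0.056) against 0.60 over all probes. Brightness was not required in the 2-day samples, so dim values there stay open. A constant shift of the probe rows in the 2-day euhydrated sample is argued against too, since the highest correlation with the control at any other offset was 0.12. Processing that differed between the pairs remains a candidate explanation: by the spread of the deposited values, which rank correlations do not use, the same pairing ranked 1 of 15, with a summed difference in SD of 0.72 against 1.45 for the next. An effect of 2 days of heat on many transcripts that has faded by 30 days, and an effect of water deprivation, stay open as biological explanations and are untested.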

How the results depend on the processing

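Of the 90 alternative counts of probes at least 2-fold different, 70 lay within 1.5 times the main count. With the values as deposited, 30 days against no heat in euhydrated rats gave 114 lower probes; hypohydration gave 223 higher and 27 lower without heat and 201 higher and 49 lower at 30 days; in hypohydrated rats 2 days against no heat gave 74 higher, and 30 days gave 1 higher and 62 lower. The median difference of all kept probes was then -0.16, 0.42, 0.43, -0.23 and -0.24 log2 units in these comparisons. Median scaling gave 96 higher at 2 days and 8 higher at 30 days in hypohydrated rats, and no filter gave 56 higher at 30 days there. The filter at the median of probe means, which tests fewer probes, gave 45 higher and 29 lower at 30 days in euhydrated rats. It gave 57 lower with hypohydration without heat, 63 higher at 2 days and 65 lower at 30 days. In hypohydrated rats it gave 79 higher at 2 days and 16 higher at 30 days, and from 2 to 30 days of heat 118 lower in euhydrated and 78 lower in hypohydrated rats. The correlations kept their sign in every alternative run. In the order of the report, the correlations of the 2-day heat, 30-day heat and 2-to-30-day changes were 0.32, 0.28 and 0.38 with the values as deposited, and those of the 2-day hypohydration change were -0.30 without heat and -0.19 at 30 days. The floor at the 25th percentile gave 0.30 and 0.37 for the 2-day and the 2-to-30-day heat changes, the filter at the median gave 0.46 and 0.48, and Spearman's rho was 0.32 and 0.35. The correlation of the hypohydration changes without heat and at 30 days was 0.66 with the filter at the median and 0.62 with normalization without the 2-day samples. For hypohydration over the 3 stages limma called 0 probes with every scaling, floor, filter and variance model run and without a block for the heat stage (unadjusted p under 0.05 at 13 to 54 probes). Leaving out 1 stage gave 0 to 154, the latter without the 2-day stage; the cause was not tested. For 2 days of heat the limma count was 53 to 93 over scalings, floors, filters and the trend, of which 10 rose and 50 fell with the values as deposited and 8 rose and 45 fell with median scaling, against 31 and 39. It was 0 to 258 when 1 sample was left out. For 30 days it was 0 in each of these, and without both 2-day samples, where 74 probes had an unadjusted p under 0.05. Of 108 alternative values of named probes 106 stayed at least 2-fold in the same direction and 0 turned. These probes were named for the largest changes, which favours such an outcome, so it says little about other probes. Probe list medians under other scalings were not run, since the probes have no gene names, and signal over background is not given. The labels give no replicate numbers, and the heat stage was the block.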

Other observations

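Hypohydration over the 3 stages was set against the other ways to split the samples, a test planned before the splits were fitted. Of the 10 splits of the 6 samples into 3 and 3, fitted with the heat stage as a block, 10 gave at least the 0 called probes of the real split, which any split reaches, and 10 splits are too few for a share under 0.05. Only 4 of the 10 part the samples of all 3 stages; the other 6 part 1 stage, rest on a single pair of samples and called 0. The highest other split called 91 probes. It set the euhydrated control, the 30-day euhydrated and the 2-day hypohydrated sample against the rest, which is the hydration split with the 2-day samples interchanged. This follows from the opposed 2-day change and points to a structure of the samples, and it gives no separate evidence on the labels.

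Changes with heat that went one way in both hydration states were more numerous than unrelated changes would give, a difference that was not tested. At 2 days 76 of 531 probes were at least 1.5-fold higher in both and 93 at least 1.5-fold lower in both, against 56.0 and 65.1 for unrelated changes. At 30 days these counts were 20 and 19, against 14.2 and 14.7. Anything shared by the alike 2-day samples raises the 2-day counts. R649 was 3.29 and 3.43 log2 units higher at 2 days, and R628 had log2 differences of -3.60 and -3.08.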
